A study of Mus musculus with 4 samples.

How the data were processed

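Total RNA of primary B lymphocytes from mouse spleen, which the labels mark with the B cell surface protein CD19, was sequenced in 4 libraries that the labels number as replicates 1 to 4 of 1 group. The mice were male, 67 days old, and F1 offspring of a C57BL/6 mother and a CAST/EiJ father. Each library started from 300 ng of RNA. The labels name an ERCC profile of synthetic spike-in RNAs for stranded libraries reduced in ribosomal RNA and link a directional library kit; how the cells were isolated is not given in the sources used here. The labels give each replicate its own biosample but the same donor identifier, so p-values measure only the spread between these samples, which may be technical.

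The authors deposited for each library a gene table, a transcript table of the same layout and a second transcript table from another quantification. Per the file headers, the first quantification has the column layout of RSEM and the second that of kallisto, and the names and versions of the tools are not given in the sources used here. The assembly is mm10 and the annotation GENCODE M21, per the text files deposited beside the tables, which were read by eye. Expected counts, the estimated number of reads per gene or transcript, were deposited by the authors without normalization. TPM, a read abundance scaled by transcript length, were deposited by the authors in both quantifications and sum to 1000000 over all features, spike-ins included. The percent of a gene's TPM on each transcript and the posterior standard deviation of each gene's count were also deposited, per the file headers; the first was recomputed here from the transcript TPM, so that it could be averaged, and the second was used only to mark genes of uncertain read assignment. Whether either quantification used the strand is not given in the sources used here, so genes that overlap an antisense partner are uncertain.

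The gene table held 81881 features, of which 55536 were Ensembl genes, all found in the annotation, 96 were spike-ins, 1 was phiX174 and 26248 were named only by a number. The numbered entries, phiX174 and the spike-ins stayed out of library sizes and tests, and the numbered entries took at most 5.68e-05% of a library's counts. In the first quantification the effective length of a gene was its length less 100 nucleotides, so 2452 short genes had an effective length of 0 and the TPM of other short RNAs is raised relative to long ones. Genes that share reads with near-identical copies, such as Rn7s1 and Rn7s2, the small nuclear RNA copies such as Rnu2-10, the hemoglobin genes, and Hspa1a and Hspa1b, are uncertain as single genes.

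Total depth was 15722742 to 17618866 expected counts per library. At this depth a count of 0 allows up to 3 counts, and this floor covers counting error only. A gene was tested between libraries when its mean count was 10 or more, which left 14020 genes, and expected counts were rounded to whole numbers first.

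With 1 group the series holds no contrast between conditions, so all comparisons are between genes, gene lists or transcripts within a library, or between the 4 libraries. The tests and 32 gene lists (cell lineages, B cell subsets, cellular programmes, immunoglobulin genes, non-coding RNAs and sex-linked genes) were set before the data were examined. Norad had no match in the annotation, and for the 3 symbols with 2 identifiers (Ccl19, Ccl21a and Rmrp) the one with the higher mean TPM was used. The genes named are the 20 with the highest mean TPM, the 10 non-coding genes with the highest mean TPM, the 3 highest members and the lowest member of each list, all immunoglobulin constant region, sex-linked and B cell transcription factor genes, and the 10 with the largest SD of log2 CPM among genes with a mean count of 100 or more. Not all of these are printed, and any other gene is said to be chosen after its values were seen.

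For lineage identity, the median log2(TPM + 1) of each lineage list was subtracted from that of the B cell list within each library, on a scale that understates differences to genes near 0, and the 4 differences were put to an exact two-sided sign-flip permutation test, whose smallest p is 0.125. Immunoglobulin and isoform compositions are percents of summed TPM per library and carry no test. Secreted and membrane transcripts of Ighm and Ighd, and Ptprc transcripts with the 3 variable exons, were read from the exons in the annotation.

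Spread between libraries was measured as the common biological coefficient of variation (BCV) from edgeR 4.0.16 in R 4.3.3, with TMM scaling and an intercept-only design. Genes were called variable between libraries when a chi-square test of a Poisson model, with 3 degrees of freedom and TMM-scaled library sizes, gave a Benjamini-Hochberg adjusted p under 0.05. This test compares libraries, not conditions, and for each list the number of members called is given over all genes and adjusted over the list alone. The SD over the libraries of each list's median log2 CPM (prior count 0.5) was compared with 10000 random lists of the same size, drawn from 20 bins of mean expression, in a gene-permutation test with Benjamini-Hochberg adjustment over the 31 lists with at least 3 tested members. Genes of a list can vary together in any sample, so these p-values describe the libraries at hand. Spearman correlations between the 2 quantifications are across genes within a library, and genes are not independent replicates.

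The steps were tested on simulated counts with the real means and depths, in 14050 genes for the chi-square test, where 200 genes were changed, and in 14024 for the BCV of 0.1 and the lists. Of genes changed 1.5-fold in 1 library the chi-square test called 61%, and 86.4% of those with a mean count of 100 or more; of genes changed 3-fold it called 86%, and of unchanged genes 0.0650%. The unchanged genes in the chi-square test carried sampling noise alone. A simulated BCV of 0.1 was recovered as 0.0998. Counts drawn with sampling noise alone gave a common BCV of 0.00988 over 14028 genes, and those with the 200 changed genes gave 0.0487, so a small share of the genes can raise the common value. Among simulated lists of 15 genes, 5.5% of unchanged ones and 92% of those raised 1.5-fold in 1 library had a p under 0.05.

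Alternatives were another pseudocount, filters on low values, TPM rescaled without spike-in, mitochondrial and immunoglobulin genes, the second quantification, the list mean, expected counts in place of TPM, size factors and median gene-wise dispersion from DESeq2 1.42.0, spike-in scaling, other count minimums, immunoglobulin genes left out, and each replicate left out in turn. After seeing the data, TPM over protein-coding genes alone, protein-coding genes alone, and leaving out genes of uncertain read assignment (a posterior standard deviation above the square root of the mean count) were added. Other computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.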

Results

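Splenic CD19 B cells of adult male F1 mice were profiled by total RNA-seq in 4 libraries of 1 group. The libraries held 17411716, 17395155, 15722742 and 17618866 expected counts in replicates 1 to 4. A mean TPM of 1 or more was reached by 12652 genes, 10090 of them among the 22028 annotated protein-coding genes. Spike-in RNAs took 0.277% ± 0.0102 of the counts (SD, n = 4). No pair of libraries agreed within counting noise, with 866 to 1505 genes called in each of 6 pairs, so none was treated as a copy of another. This does not show that the samples are separate, since libraries of the same RNA can differ as well.

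Structured non-coding RNAs dominated the TPM scale, which favours short transcripts. The 7SL genes Rn7s1 and Rn7s2, RNA components of the signal recognition particle, were each listed at 142246 ± 8103 TPM (SD, n = 4); both had the same value in every library and share reads, so neither level belongs to a single gene. Rn7sk, which restrains transcription elongation, followed at 70095 ± 1031 TPM. Next came the mitochondrial ribosomal RNAs mt-Rnr2 at 30930 ± 861 and mt-Rnr1 at 22339 ± 931 TPM. Gm26917 (chromosome 17, 39843013 to 39846341, mm10), annotated as a lincRNA, was at 29758 ± 2343 TPM. Which RNA its reads derive from was not tested. The RNA components of RNase P, Rpph1, and RNase MRP, Rmrp, stood at 15162 ± 924 and 10398 ± 287 TPM. Only 2 of the 20 highest genes were protein-coding: Cd74, the invariant chain of MHC class II, at 5372 ± 230 TPM and the ribosomal protein gene Rps27 at 3310 ± 99.98 TPM. By expected counts, protein-coding genes took 68.7% ± 0.763 and genes annotated as lincRNAs, Gm26917 among them, 11.7% ± 0.364.

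The long non-coding list had a median of 44.8 ± 4.13 TPM over 12 members, led by Malat1 at 5902 ± 239, Gas5 at 199 ± 10.5 and Neat1 at 123 ± 14.1 TPM, while Meg3 had a count of 0 in every library. The structured small RNA list had a median of 10398 ± 287 TPM over 9 members. Of the sex-linked genes, the Y-linked Eif2s3y, Ddx3y, Kdm5d and Uty were at 46.4 ± 6.04, 33.4 ± 4.07, 15.73 ± 1.92 and 15.71 ± 2.59 TPM and Xist at 0.0375 ± 0.0206 TPM, which matches the male label, with a list median of 16.1 ± 2.31 TPM.

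Which lineage the RNA came from was asked by setting the B cell list against 8 other lineage lists. All 20 B cell genes had a mean above 10 TPM, with a list median of 252 ± 16.0 TPM (SD, n = 4). The antigen receptor signalling chains Cd79a and Cd79b were at 610 ± 19.8 and 580 ± 30.1 TPM, the inhibitory receptor Cd22 at 432 ± 31.1 TPM, and Tnfrsf13c, the receptor for the survival factor BAFF, was the lowest named member at 124 ± 10.3 TPM. Cd19, the gene of the surface protein named in the labels, was at 422 ± 25.1 TPM. The B cell list exceeded the monocyte and macrophage list by 6.12 ± 0.23 on the log2(TPM + 1) scale, the T cell list by 6.86 ± 0.15, the NK cell list by 7.05 ± 0.38, the erythroid list by 7.28 ± 0.19, the neutrophil list by 7.38 ± 0.20, the dendritic cell list by 7.55 ± 0.11, the megakaryocyte and platelet list by 7.77 ± 0.25 and the stromal and endothelial list by 7.91 ± 0.11. Each difference was positive in 4 of 4 libraries, which gives the smallest p that the exact sign-flip test allows with n = 4, a value above 0.05. The differences exceeded the SD between libraries many times over.

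**Figure D1:**
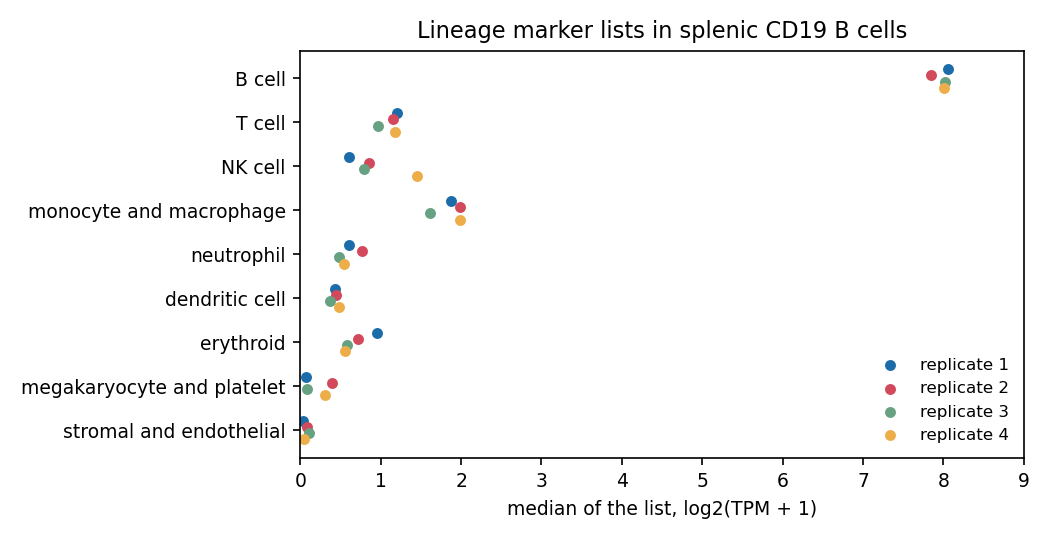
Median log2(TPM + 1) of each lineage marker list (x axis) in the 4 libraries, 1 point per replicate, with the lists on the y axis. The B cell list lies at 7.84 to 8.05 in the 4 libraries, and the highest of the other lists, monocyte and macrophage, at 1.61 to 1.99.

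Low levels of markers of other lineages were present. In the T cell list (median 1.19 ± 0.156 TPM) 10 of 16 genes reached a mean of 1 TPM, with the kinase Lck at 10.7 ± 1.42 TPM and the T cell receptor constant gene Trbc2 at 3.62 ± 0.784 TPM, and Cd8b1 was lowest at 0.263 ± 0.168. The monocyte and macrophage list (median 2.67 ± 0.431 TPM) was led by Hmox1, Adgre1 and Csf1r at 4.49 ± 0.992, 4.29 ± 0.949 and 4.14 ± 0.786 TPM. The NK cell list had a median of 0.95 ± 0.541 TPM, with the pore-forming protein gene Prf1 at 4.09 ± 0.371 and the cytokine receptor chain Il2rb at 2.75 ± 1.32 TPM. In the erythroid list (median 0.713 ± 0.294 TPM) the hemoglobin genes Hba-a1, Hbb-bs and Hba-a2 stood out at 72.0 ± 31.6, 62.0 ± 28.8 and 48.3 ± 22.1 TPM. Medians were 0.523 ± 0.135 TPM for the neutrophil list, 0.348 ± 0.0419 for the dendritic cell list, 0.169 ± 0.139 for the megakaryocyte and platelet list and 0.0475 ± 0.0275 for the stromal and endothelial list. In the last of these, Pecam1 was at 85.3 ± 6.68 TPM while 14 of 15 members had a mean under 1 TPM.

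Among B cell subset lists, follicular B genes were highest, with a median of 231 ± 17.9 TPM over 6 members. They included Ighd at 805 ± 60.05, Klf2, a regulator of lymphocyte trafficking, at 661 ± 110 and the low-affinity IgE receptor Fcer2a at 247 ± 23.4 TPM. The marginal zone B list had a median of 24.1 ± 4.32 TPM, with the complement receptor Cr2, which is also in the B cell list, at 358 ± 30.6, Notch2 at 96.4 ± 7.70 and Cd9 lowest at 6.37 ± 1.45 TPM. The transitional B list (median 46.0 ± 5.55 TPM) ran from Cd24a at 219 ± 12.4 to Cd93 at 2.98 ± 0.232 TPM. The plasma cell list had a median of 7.71 ± 0.801 TPM, with Irf4 at 144 ± 8.66, Xbp1 at 36.2 ± 5.34 and the joining chain gene Jchain at 23.7 ± 2.53 TPM. Medians were 1.03 ± 0.417 TPM for B1 and age-associated B genes, 0.6 ± 0.182 for germinal centre B genes and 0.09 ± 0.0648 for pro-B and pre-B genes. In the germinal centre list, Bcl6 at 26.7 ± 2.07 TPM contrasted with Aicda, the deaminase of class switching and somatic hypermutation, at 0.463 ± 0.114 TPM. No pro-B or pre-B gene reached a mean of 1 TPM; the recombinase gene Rag1 was at 0.235 ± 0.114 and Dntt at 0.0275 ± 0.0320 TPM.

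The 24 transcription factors of B cells had a median of 117 ± 8.37 TPM, and 22 had a mean above 10 TPM. Klf2 led, followed by Pax5, the B lineage commitment factor, at 375 ± 37.0, Foxp1 at 335 ± 37.6, Mef2c at 251 ± 18.1, Ets1 at 243 ± 16.3 and Ikzf3 at 231 ± 20.7 TPM. Spib, Ebf1, Pou2af1, Irf8, Bach2 and Ikzf1 lay between 115 and 161 TPM, and Bcl11a, Tcf4, Pou2f2, Tcf3, Foxo1, Spi1 and Id3 between 22.8 and 99.7 TPM. Prdm1, which drives plasma cell differentiation, was at 1.54 ± 0.429 TPM.

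The MHC class II list had a median of 346 ± 24.9 TPM, with H2-Ab1 and H2-Aa at 2010 ± 160 and 1492 ± 92.6 TPM, and the MHC class I list one of 85.1 ± 6.00 TPM, led by H2-K1 at 899 ± 38.0 TPM. B cell receptor signalling genes (median 116 ± 8.37 TPM) all had a mean above 10 TPM, and homing and cytokine receptors had a median of 72.7 ± 5.13 TPM, with the lymph node homing receptor Sell at 214 ± 14.0 and Ccr7 at 127 ± 12.7 TPM. Immediate early genes (median 81.3 ± 2.91 TPM) were abundant in these isolated cells, with the AP-1 subunits Jund, Fosb and Fos at 472 ± 70.1, 354 ± 147 and 321 ± 102 TPM. Other medians were 37.6 ± 8.39 TPM for heat shock, 18.4 ± 1.33 for apoptosis regulators, 7.10 ± 0.7005 for Toll-like receptors, 2.81 ± 1.63 for interferon-stimulated and 1.79 ± 0.129 for proliferation genes. Within them, the anti-apoptotic Mcl1 was at 142 ± 5.47, Cd180 at 201 ± 26.6, Pcna at 90.6 ± 2.43 and the mitotic kinase gene Bub1 at 0.27 ± 0.0942 TPM.

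Heavy chain constant RNA was almost entirely Ighm and Ighd, and light chain constant RNA came from both the kappa and the lambda genes. Of heavy chain constant TPM (list median over 8 genes 2.95 ± 0.820), Ighm (chromosome 12, 113418558 to 113422730) took 74.0% ± 0.790 and Ighd (chromosome 12, 113406604 to 113416324) 25.0% ± 0.818 (SD, n = 4). The switched isotypes together took 1.05% ± 0.266, of which Ighg3 gave 0.794% ± 0.201, Ighg2b 0.104%, Igha 0.0709%, Ighg2c 0.0605% and Ighg1 0.0160%. Ighe had counts in 1 library only, with a mean count of 0.25. Of light chain constant TPM (list median over 5 genes 887 ± 34.3), Igkc (chromosome 6, 70726435 to 70726966) took 55.7% ± 0.642. The lambda genes on chromosome 16 took 44.3% ± 0.642, with Iglc1 at 19.8% ± 0.346, Iglc2 at 19.2% ± 0.644, Iglc3 at 5.21% ± 0.166 and Iglc4 at 0.0526% ± 0.0107. These percents rest on at least 18383 counts for Igkc and 12287 for the lambda genes in each library. By the TPM of variable (V) segments, chosen after their values were seen, the lambda share was only 8.09% ± 0.354. The constant region share therefore does not by itself give the use of kappa and lambda chains.

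**Figure D2:**
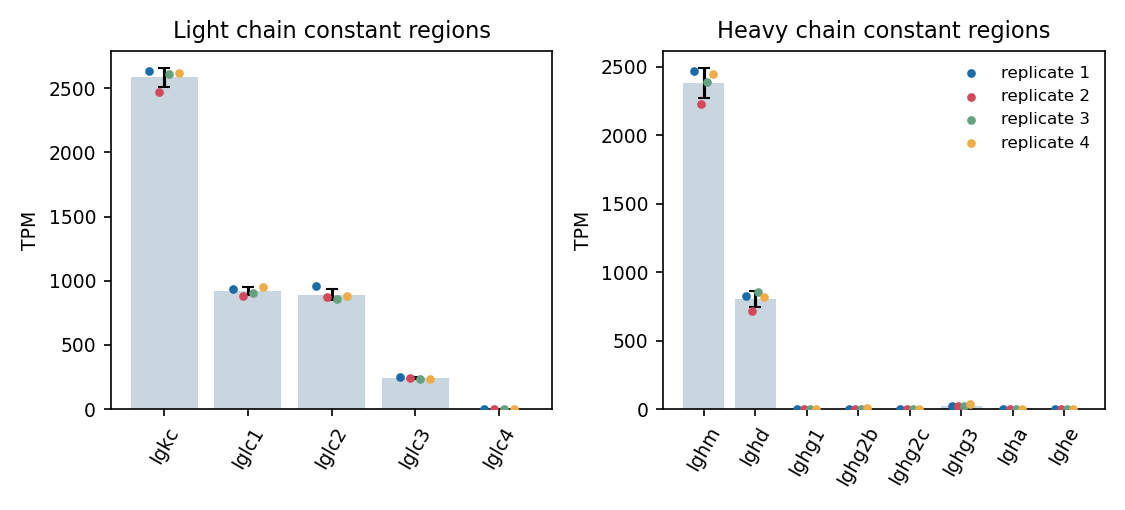
TPM of the light chain (left) and heavy chain (right) immunoglobulin constant genes; bars are means of the 4 libraries, error bars the SD, and points the replicates. Igkc averages 2584 TPM against 920 for Iglc1 and 892 for Iglc2, and Ighm 2382 TPM against 805 for Ighd and 25.7 for Ighg3.

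Most Ighm and Ighd transcripts encoded the membrane form. The Ighm transcript with the membrane exons (chromosome 12, 113418558 to 113418834 and 113418953 to 113419068) took 71.1% ± 0.627 of the gene's TPM and the secreted form 28.9% ± 0.627, and the second quantification gave 71.3% ± 0.906 for the membrane form. For Ighd the membrane transcript took 91.5% ± 1.85. In both genes the sequence found only in the secreted transcript lies within an intron of the membrane transcript. For Ighm it runs from 113420741 to the shared exon that starts at 113420929, and for Ighd from 113409552 to 113409645. Unspliced RNA in these total RNA libraries could therefore be counted as secreted, which was not tested. Ptprc encodes the phosphatase CD45, and the transcript with all 3 variable exons (chromosome 1, 138117754 to 138117894, 138120020 to 138120166 and 138122456 to 138122584), the B220 form typical of B cells, took 41.4% ± 1.76. Protein-coding Ptprc transcripts with none of these exons took 1.64% ± 1.00. The short protein-coding transcript Ptprc-212, which lacks the exon at 138120020 to 138120166, took 21.6% ± 2.23. As annotated it stops at 138117838, inside the variable exon at 138117754 to 138117894, and holds none of the exons beyond. Since TPM is raised for short transcripts, this percent does not give the share of a full-length form without that exon. The remaining TPM of the gene lay on its other annotated transcripts. Among 159 list genes with at least 2 transcripts and a mean of 1 TPM or more, the leading transcript was the same in all 4 libraries for 124 and the same in both quantifications for 117. For 15 of the 159 genes the leading transcript was annotated as a retained intron.

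Between libraries, expression was close but not identical. The common BCV was 0.0788 over 14020 genes (0.0350 as the DESeq2 median gene-wise value), and 0.0220 over 34 spike-in features, which carry no biology. In simulated counts sampling noise alone gave 0.00988, and 200 genes changed in 1 library gave 0.0487, so the common value need not describe most genes. The chi-square test called 2988 of 14020 genes (21.3%) variable beyond counting noise, and 6 of the 34 spike-in features. Without replicate 2 the count of genes was 1804. The spike-in features, though few, were called at a rate not far below that of the genes. A call by this test therefore does not by itself show a biological difference. The same limit holds for the numbers of list members called in the paragraphs below. Of the called genes, 598 had a range above 1 on the log2 CPM scale, and 397 had uncertain read assignment. Called genes had their highest value in replicates 1 to 4 in 743, 974, 675 and 596 cases.

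The heat shock list set replicate 2 apart. Its median log2 CPM was 7.13 there against 6.15, 6.15 and 6.14 in replicates 1, 3 and 4 (adjusted p = 0.00155 in the gene-permutation test, whose smallest unadjusted p is 0.0001). All 10 members had their highest CPM in replicate 2, and 9 varied beyond counting noise over all genes, 10 adjusted over the list alone. Hspa8, a constitutive chaperone, was at 349 ± 43.9 TPM, Hsp90aa1 at 175 ± 14.2 and Dnaja1 at 88.2 ± 14.6 TPM. Hspa1b and Hspa1a, inducible Hsp70 genes chosen after their values were seen, had 2852 and 1017 counts in replicate 2 and at most 209 and 126 in the others, and they share reads. Without replicate 2 the list no longer passed, with an SD of 0.00491 and an adjusted p of 0.986. The megakaryocyte and platelet list was also higher in replicates 2 and 4, at 1.37 and 1.48 against 0.08 and 0.02 log2 CPM in replicates 1 and 3. The monocyte and macrophage list was highest in replicate 2, at 2.48 against 1.66 to 2.15, with 9 of 13 tested members highest there.

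**Figure D3:**
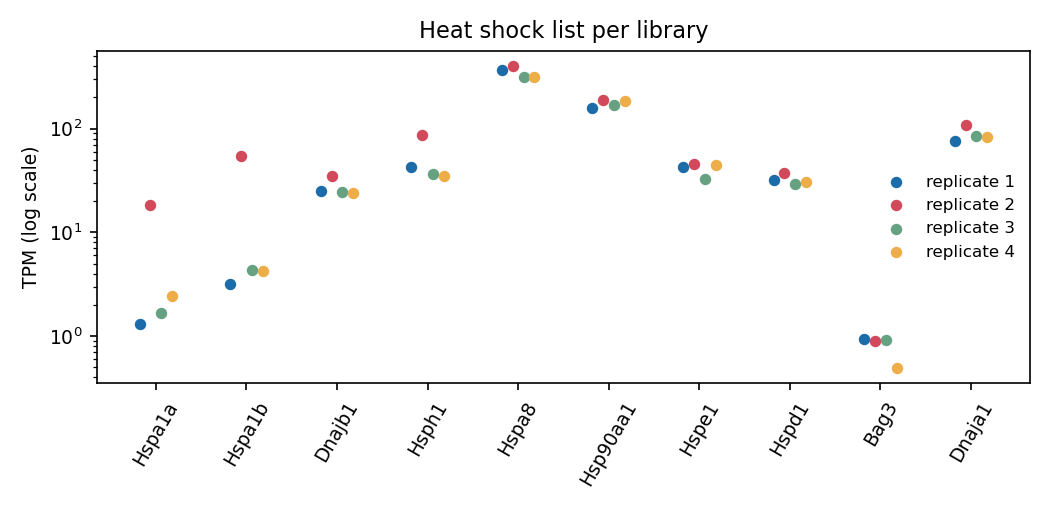
TPM (y axis, log scale) of the 10 heat shock list genes (x axis) in each library, 1 point per replicate. Hspa1b is at 54.0 TPM in replicate 2 and at 3.15 to 4.29 TPM in the others.

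Interferon-stimulated genes were highest in replicate 1. The list median was 3.51 log2 CPM there against 2.57, 2.54 and 2.52 in replicates 2, 3 and 4 (adjusted p = 0.0031 in the gene-permutation test). Of 19 tested members 18 had their highest CPM in replicate 1, and 16 varied beyond counting noise over all genes, 17 adjusted over the list alone. Stat1 was at 69.4 TPM in replicate 1 and at 49.8 to 56.9 in the others, and Mx2, an antiviral GTPase, at 18.81 against 8.64 to 10.6 TPM. Immediate early genes were lowest in replicate 1 by list median, at 7.63 log2 CPM against 7.93 to 7.98 (adjusted p = 0.00744), although by TPM the median was highest there. Members went both ways, with 15 of 18 tested called over all genes and 15 adjusted over the list alone. Fosb was at 181, 290, 434 and 510 TPM in replicates 1 to 4 and Fos at 201, 272, 389 and 421 TPM, while Dusp2, chosen after its values were seen, was at 258, 227, 223 and 208 TPM. Erythroid genes were highest in replicate 1 in 5 of 6 tested members (adjusted p = 0.00744; 5 called over all genes, 6 adjusted over the list alone), with Hba-a1 at 116 TPM there and 44.2 to 71.4 in the others. Without replicate 1 none of these 3 lists passed, with adjusted p of 0.982 for interferon-stimulated, 0.758 for immediate early and 0.758 for erythroid genes, and the erythroid list was also lost without replicate 2 (0.0936) or replicate 3 (0.0675).

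NK cell genes differed most firmly between libraries. The list median was 1.18 log2 CPM in replicate 4 and 0.84 in replicate 2, against -0.05 in replicate 1 and -0.27 in replicate 3 (adjusted p = 0.00155 in the gene-permutation test). All 10 tested members were highest in replicate 4, and 8 were called over all genes, 9 adjusted over the list alone. Il2rb was at 4.65 TPM in replicate 4 and at 1.78 to 2.61 in the others, while Prf1 was at 3.59 to 4.47 TPM and was not called. This list alone kept its call under all 6 alternatives. Other lists moved in the same libraries: megakaryocyte and platelet genes were at 1.48 and 1.37 in replicates 4 and 2 against 0.08 and 0.02, and dendritic cell genes, which did not pass, at 0.41 and 0.41 against 0.07 and 0.07.

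The remaining 4 lists that passed did so narrowly. They were marginal zone B (adjusted p = 0.0430; 10 of 11 members called, 10 adjusted over the list alone), structured small RNA (0.0430; 6 of 7, 7 adjusted over the list alone), monocyte and macrophage (0.0458; 6 of 13, 7 adjusted over the list alone) and megakaryocyte and platelet genes (0.0458; 3 of 4, 4 adjusted over the list alone). The marginal zone B median was 5.75 log2 CPM in replicate 3 against 6.00 to 6.14 in the others, and all 7 tested small RNAs were highest in replicate 2. Each of these calls was lost under spike-in scaling and without some replicates. The marginal zone call was lost without replicate 1 (adjusted p = 0.0550) or 3 (0.293), the small RNA call without replicate 1 (0.111), 2 (0.0936) or 3 (0.0522), the monocyte and macrophage call without replicate 2 (0.206) or 3 (0.255), and the megakaryocyte and platelet call without replicate 1 (0.0688), 2 (0.0936) or 4 (0.0941). In all, 9 of 31 lists passed, 13 before adjustment, and 3 to 9 passed with 1 replicate left out.

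**Figure D4:**
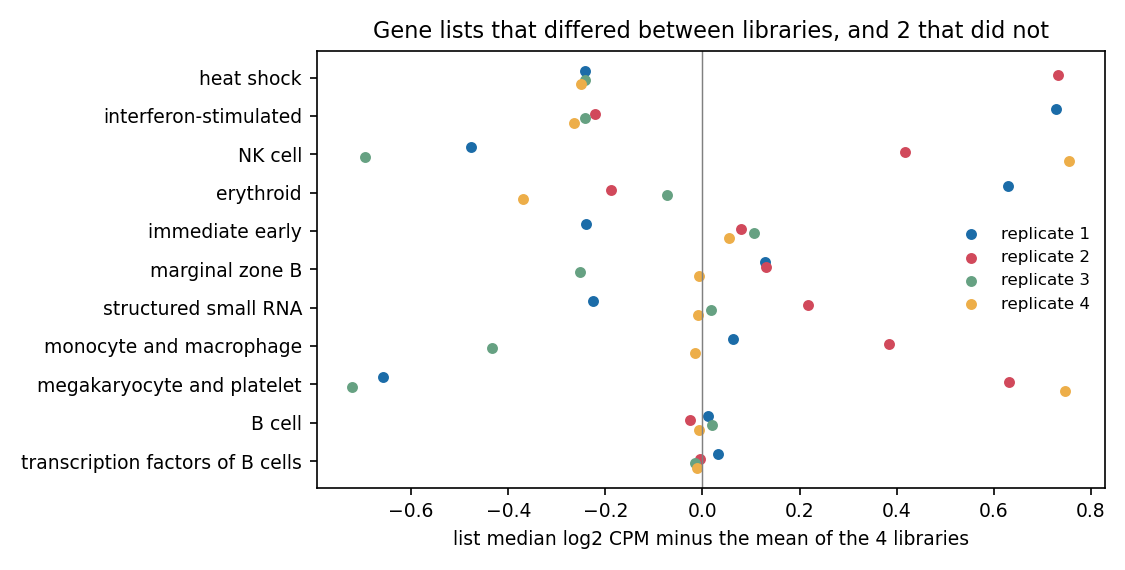
Median log2 CPM of each list minus its mean over the 4 libraries (x axis), 1 point per replicate, for the 9 lists that passed and for the B cell and B cell transcription factor lists. Replicate 2 stands apart for heat shock and replicate 1 for interferon-stimulated genes, while the SD is 0.02 for the B cell list under TMM scaling.

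The lists that define the B cell identity showed no such difference. The B cell list had an SD of 0.02 log2 CPM between libraries (adjusted p = 0.777 in the gene-permutation test), the B cell transcription factors 0.02 (0.747) and B cell receptor signalling genes 0.03 (0.533). Spike-in scaling raised these SDs to 0.08, 0.06 and 0.04, and none of the 3 lists was called under any alternative. Individual members still varied by small amounts: 14 of 20 B cell genes, 13 of 24 transcription factors and 12 of 20 signalling genes were called over all genes, and 14, 16 and 14 adjusted over the list alone. Members called over all genes and adjusted over the list alone were 10 and 10 of 11 for MHC class II, 5 and 5 of 9 for MHC class I, 14 and 14 of 19 for homing and cytokine receptors, 5 and 5 of 12 for Toll-like receptors, 4 and 4 of 12 for apoptosis regulators and 3 and 3 of 16 for proliferation. They were 5 and 5 of 6 for follicular B, 3 and 3 of 3 for transitional B, 1 and 1 of 7 for germinal centre B, 3 and 4 of 8 for plasma cell, 2 and 3 of 6 for B1 and age-associated B, and 1 and 1 of 2 for pro-B and pre-B genes. For the T cell, neutrophil, dendritic cell, and stromal and endothelial lists they were 1 and 0 of 15, 1 and 1 of 6, 2 and 2 of 5, and 1 and 1 of 3. For Ig heavy constant, Ig light constant, sex-linked and long non-coding genes they were 5 and 5 of 7, 4 and 4 of 4, 4 and 4 of 4, and 3 and 4 of 11.

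The 10 genes with the largest SD of log2 CPM between libraries were mt-Co2 (5.14), Tspan10 (5.01), Gm10335 (4.58), 1700047I17Rik2 (4.31), Gm10132 (4.24), Nnt (4.17), Hist1h2ap (4.16), Gm10163 (3.28), Pagr1a (2.06) and Eps8l1 (2.06). For 8 of them the deposited standard deviation of read assignment was at least 4.22 times the counting error, so their values are uncertain. For Tspan10 (chromosome 11, 120442644 to 120446950), a tetraspanin gene, and Eps8l1 (chromosome 7, 4460674 to 4480487) it was 0. Tspan10 had 0, 256, 375 and 1 counts and Eps8l1 194, 248, 15 and 432 counts in replicates 1 to 4.

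The 2 quantifications ranked genes alike within a library. Spearman's rho across 55450 genes was 0.848 to 0.852, and 0.974 to 0.976 across the protein-coding genes at 1 TPM or more in either. They parted on short RNAs: the second gave a count of 0 for small nuclear RNAs, which held 8.01% ± 0.597 of the TPM in the first.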

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

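All tests of explanations in this part were chosen after the result was seen. Of 230 values per library, 20 had a highest or lowest library set apart by a gap that was large against the range of all 4, where chance alone gives about 1 in 20, or 11.5. The number quoted for each is that gap divided by the range. Replicate 4 was the highest in 8 of the 20.

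The heat shock list (gap 0.991) was highest in replicate 2, with a median of 7.13 log2 CPM against 6.14 to 6.15. Reads shared between Hspa1a and Hspa1b do not account for it, since all 8 of the other 8 members were highest in replicate 2 as well. Neither does scaling: the SD of the list median was 0.489 under TMM, 0.489 under DESeq2 size factors and 0.439 under spike-in scaling. Hspa1b in replicate 2 exceeded the mean of the others by at least 3.88 (log2) under 4 scalings. That test of 1 member could hardly fail, since spike-in scaling shifted the median gene by up to 0.15 (log2) only. The list medians argue against a larger share of cells of another listed lineage alone, though the limits of this test were set after they were seen. The megakaryocyte and platelet, NK, and monocyte and macrophage lists were raised in replicate 2 by 0.84, 0.56 and 0.51 (log2). Over the other libraries these lists spanned 1.47, 1.45 and 0.50 while the heat shock list spanned 0.00908. A response within such cells cannot be told apart from a response of the B cells, since no table separates the RNA by cell type. No biological explanation was tested, because the design has 1 group.

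The switched isotypes (gap 0.921) were highest in replicate 4, at 1.44% of heavy chain constant TPM against 0.893% to 0.937%. Ighg3 (0.92) was at 1.09% against 0.682% to 0.715%. Ighe had a count in replicate 4 only (gap 1, in TPM and in percent), which is below the 3 counts that a count of 0 allows. The B1 and age-associated B list (0.938) was highest in replicate 4, at 1.83 log2 CPM against 1.03 to 1.08, but only 2 of its 6 tested members were, and its spread was not called (adjusted p = 0.209 in the gene-permutation test). Highest there too was its member Itgax (0.923), also in the dendritic cell list, at 1.87 against 0.44 to 0.55 TPM. Elane (0.833) was at 0.12 against 0.06 to 0.07 TPM and Treml1 (gap 1) at 0.06 against 0 TPM in the same library, both near the floor. Bag3 (0.889) was lowest in replicate 4 by TPM, at 0.49 against 0.89 to 0.94.

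The interferon-stimulated list (0.957) was highest in replicate 1, at 3.51 log2 CPM against 2.52 to 2.57, and the immediate early list (0.85) lowest, at 7.63 against 7.93 to 7.98. Rps27 (0.837), Itgb3 (0.885) and Spi1 (0.857) were highest in replicate 1, at 3459, 8.71 and 39.4 TPM against at most 3280, 8.17 and 32.5, but by CPM all 3 were highest in replicate 2. The follicular B list (0.917) was highest in replicate 3, at 9.18 against 9.05 to 9.06 log2 CPM, as were 5 of its 6 members, and its spread was not called (adjusted p = 0.274 in the gene-permutation test). Replicate 2 was lowest for Ets1 (0.84), at 219 against 249 to 255 TPM, for Igkc (0.842), at 2472 against 2610 to 2636 TPM, and for Ptprc transcripts with all 3 variable exons (0.841), at 38.8% against 42.0% to 42.6%. By CPM, in contrast, Igkc was highest in replicate 2 and Ets1 lowest in replicate 1. Total expected counts (0.882) were lowest in replicate 3.

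Outside the measured genes, phiX174 held a mean of 52.75 expected counts per library (42 to 71), above the 3 counts that a count of 0 allows. Of the entries named only by a number, the highest had 4 counts in a library, barely above that limit, which shows little with so many entries.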

How the results depend on the processing

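TPM over protein-coding genes alone, protein-coding genes alone and genes of uncertain read assignment left out were chosen after seeing the data. No difference between the B cell list and another lineage list changed sign under the alternatives. Percents, TPM, SDs, the BCV and counts cannot change sign, so for them the lack of a reversal shows nothing. The order of the libraries by TPM against CPM and the order of V segments were not put to the alternatives. Of the alternatives to the main results, 150 were rated unchanged, 42 moved and 20 lost a call. For single genes and lists 972 were rated unchanged, 341 moved and 2 gained a call. Unchanged meant within the spread between libraries or on the same side of the threshold, but numbers of genes had a wider tolerance. Among those rated unchanged were 17742 genes at 0.1 TPM or more against 12652 at 1 TPM or more. So were 2176 genes called variable without replicate 1 against 2988 with all libraries. TPM over protein-coding genes alone moved all 166 named genes with a mean above 0 by over 1.5-fold (median ratio 2.86), and the second quantification 43 of the 166 (median ratio 1.22), so TPM levels depend on the quantification and on the genes included. Without replicates 1, 2, 3 and 4 in turn, 5, 2, 2 and 7 of the 166 changed by over 1.5-fold. The cause of each change was not tested unless named. Depth limits genes near 10 counts, where fewer changes can be called.

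The B cell list stayed above every other list under each alternative. With a pseudocount of 0.1 the log2 differences were 7.62 for the T cell, 8.03 for the NK cell, 6.52 for the monocyte and macrophage, 8.71 for the neutrophil, 9.14 for the dendritic cell, 8.61 for the erythroid, 10.09 for the megakaryocyte and platelet and 10.76 for the stromal and endothelial list, as a smaller pseudocount lowers values near 0. With TPM over protein-coding genes alone they were, in the same order, 7.37, 7.68, 6.40, 8.20, 8.50, 8.08, 8.98 and 9.31. The second quantification gave 6.66 for T cell and 6.86 for erythroid genes. The list mean gave 6.42 for monocyte and macrophage, 7.14 for neutrophil, 5.90 for erythroid, 7.26 for megakaryocyte and platelet and 7.42 for stromal and endothelial genes, and leaving out members under 0.1 TPM gave 5.90, 7.05 and 7.53 for the last 3.

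By expected counts the lambda share was 40.9%, Ighm 73.1% and Ighd 26.0%; the second quantification gave a lambda share of 41.8%, an Ighd membrane form of 89.3% and 36.0% for Ptprc with all 3 variable exons. The spike-in share by TPM was 0.362%. The BCV was 0.0711 at a mean count of 100 or more, 0.0657 in protein-coding genes, 0.0585 without genes of uncertain read assignment and 0.0350 as the DESeq2 median gene-wise dispersion, which is not a common value; moves were judged against its jackknife SE of 0.00567, and it was 0.0735 to 0.0821 with 1 replicate left out. Genes called variable numbered 1804 to 2452 with 1 replicate left out, where fewer samples enter the test.

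Spike-in scaling shifted the median gene by up to 0.15 (log2) between libraries and left 5 lists called. It ended the calls of the monocyte and macrophage (SD 0.27, adjusted p = 0.190), megakaryocyte and platelet (0.76, 0.0739), marginal zone B (0.13, 0.224) and structured small RNA (0.16, 0.0806) lists. With 1 replicate left out 3 to 9 lists were called, and the SD was 0.615 to 0.782 for NK cell, 0.213 to 0.412 for monocyte and macrophage, 0.153 to 0.477 for erythroid, 0.764 to 0.830 for megakaryocyte and platelet, 0.0792 to 0.221 for marginal zone B, 0.0261 to 0.193 for immediate early, 0.00491 to 0.566 for heat shock, 0.0215 to 0.566 for interferon-stimulated and 0.123 to 0.222 for structured small RNA genes. Adjusted p in these fits with 1 replicate left out ran from 0.0031 to 0.0252 for NK cell genes, from 0.00155 to 0.986 for heat shock and from 0.00155 to 0.982 for interferon-stimulated genes. The lists of B cell identity were called under no alternative. Their SDs under spike-in scaling were 0.0807 for B cell, 0.0608 for B cell transcription factor and 0.0432 for B cell receptor signalling genes, and with 1 replicate left out 0.0132 to 0.0237, 0.00505 to 0.0258 and 0.00745 to 0.0413. The Toll-like receptor list gained a call without replicate 2 (adjusted p = 0.0490) or replicate 4 (adjusted p = 0.0303).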

Other observations

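All tests in this part were chosen after the result was seen, except that of the 10 genes with the largest SD between libraries against the second quantification. The histone genes, V segments and single genes named here were chosen after their values were seen.

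Histone transcripts, many of which lack a poly(A) tail and are seen in total RNA, were abundant. The 67 genes with symbols starting with Hist summed to 3144 ± 152 TPM (SD, n = 4), and 62 had a mean of 1 TPM or more. The linker histone genes Hist1h1c and Hist1h1e were at 298 ± 10.97 and 128 ± 9.82 TPM, and the core histone genes Hist2h2aa2 and Hist1h2bg at 251 ± 16.1 and 206.5 ± 20.3 TPM, though near-identical copies share reads. In the second quantification Hist2h2aa2 was at 155 ± 97.4 TPM, from 46.5 to 264 across libraries. Hist1h1c, Hist1h1e and Hist1h2bg were at 265, 128 and 211 TPM there. Over the same libraries the median of the proliferation list was 1.79 ± 0.129 TPM. A sum over short genes and a list median are unlike measures, so the 2 cannot be compared in size.

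V segments of the immunoglobulin loci were diverse. At least 10 mean counts were found for 96 of 160 kappa V segments, 96 of 185 heavy V segments and all 3 lambda V segments. Segments were taken by symbol, so annotated pseudogenes are counted among them. Reads of parental alleles that differ from the assembly may be lost or assigned to another segment, so single segments and their levels are uncertain. The heavy segments Ighv3-2 and Ighv4-2, both annotated as pseudogenes, were at 90.5 ± 8.33 and 78.2 ± 4.85 TPM. In the second quantification Ighv4-2 was at 8.04 TPM. The kappa segments Igkv1-110 and Igkv10-96 were highest in the first quantification, at 103 ± 2.78 and 101 ± 5.48 TPM, followed by the heavy segment Ighv14-2 at 93.4 ± 13.4 TPM. Iglv1, Iglv3 and Iglv2 were at 71.7 ± 7.48, 67.6 ± 7.86 and 52.1 ± 7.75 TPM. The order differed in the second quantification, where Igkv1-117 at 126.5 and Iglv3 at 113.5 TPM exceeded Igkv1-110 at 79.4 TPM.

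The lambda share was 44.3% of light chain constant TPM but 8.09% ± 0.354 of light chain V segment TPM. Short genes raising TPM do not account for the high constant share, since lambda still took at least 40.1% of the expected counts in each library. V segment TPM per constant region TPM was 0.0931 ± 0.00571 for lambda, 0.841 ± 0.00861 for kappa and 0.528 ± 0.00675 for the heavy chain, so lost Igkc reads of 1 parental allele, which leave the lambda ratio as it is, would not account for its low value. Whether such a loss adds to the high constant share was not tested, since the use of each allele is not known. RNA with no annotated V segment and lost reads of lambda V segments were not tested and stay open. No biological explanation was tested, because the design has 1 group.

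The 10 genes with the largest SD between libraries were set against reads shared with near-identical copies, which could make such genes vary. By the test written beforehand, 5 of the 10 had under 50% of their SD in the second quantification, which left the matter undecided because at least 6 were needed. Shared reads stay open for the 8 with a read-assignment SD above the counting error, since in the second quantification the SD fell from 5.14 to 0.48 for mt-Co2 but rose from 3.28 to 4.54 for Gm10163. For Tspan10 and Eps8l1, whose read-assignment SD was 0, the second quantification kept at least 0.795 of the SD, which argues against shared reads. Tspan10 was at 0, 8.42, 14.96 and 0.03 TPM and Eps8l1 at 6.26, 7.57, 0.96 and 16.5 TPM in replicates 1 to 4; no biological explanation was tested.

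The second quantification gave 1.12 ± 0.00275 times the summed counts of the first over protein-coding genes, 1.88 ± 0.0114 over antisense genes and 0.515 ± 0.0623 over miscellaneous RNAs. The median ratio of single genes was 1.12 over protein-coding genes, 1.12 over 262 antisense genes and 0.137 over 25 miscellaneous RNAs. For antisense genes and miscellaneous RNAs the sums therefore do not describe a typical gene.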
